A study of Mus musculus with 14 samples.

How the data were processed

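The series profiled 2 histone marks in mouse regulatory T cells by CUT&Tag, an assay in which an antibody tethers a transposase to chromatin so that fragments bearing the mark are cut out and sequenced. H3K27ac marks active promoters and enhancers, and H3K27me3 is the repressive mark set by Polycomb complexes. Per the labels' protocols, the cells were sorted by FACS from control chimeras and from chimeras with Slc31a1 deleted in the regulatory T cells that carry the Foxp3-YFP-Cre allele, and 140000 cells entered each sample. Slc31a1 encodes CTR1, the main copper importer of the cell surface. Of 14 samples, 10 had a peak list: H3K27ac for 3 control and 3 knockout chimeras, and H3K27me3 for 2 control and 2 knockout chimeras. The 4 IgG samples, 3 control and 1 knockout, had no list and were not analysed here. The labels number the chimeras and the design text speaks of different mice, but no label ties each sample to a separate animal, so that p-values measure the spread between these samples.

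Per the submitters' processing notes, the tools used on the reads were Bowtie2 2.2.4, deepTools 3.5.1, MACS2 with no version given, ChIPseeker 1.30.3 and HOMER 4.11, with genome build mm39. Which settings were used, whether an IgG library served as background and how duplicates were treated is not given in the sources used here. Each list belongs to 1 library, so peaks were called per sample. Each row of the deposited lists holds the start and end of a peak and its summit offset. It also holds the authors' score, a whole number equal to 10 times the −log10 p with the decimals dropped. The fold enrichment of a peak over its local background was deposited as a ratio. The authors' p and q values were deposited as −log10. These values belong to a peak within its own list. They were used here to describe, rank or filter peaks within that list, to choose which regions to name by their mean −log10 p over the lists of 1 genotype, and to read back depth and background. Reads and counts per region were not used here, and a peak list states the presence and length of enrichment, not its strength.

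Peaks on the 19 autosomes, X and Y were used as deposited. Coordinates are those of mm39, counted from 1. The gene table at hand is of GRCm38.p6, another build, and was used only to look up the chromosome of Slc31a1. No annotation of mm39 was used, so no peak was assigned to a gene, and the planned tests of genes, promoters, genomic location and 27 gene lists were replaced, as fixed beforehand for this case, by a test of 10 kb bins. Overlaps counted from 1 bp. Regions were the merged union of all peaks of a mark. For each library the number of peaks, the bases under peaks and the median width were compared between genotypes by a two-sided exact permutation test of the difference of means, which cannot give a p under 0.1 for 3 against 3 libraries or under 0.33 for 2 against 2. The similarity of libraries was the Jaccard index of the bases under peaks. Regions with a peak in every library of one genotype and none of the other were counted for the real grouping and for every other split into equal groups, 10 splits for H3K27ac and 3 for H3K27me3, the real one included.

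For each 10 kb bin, the bases under peaks in each library were taken as log2(bases + 100), centred on the median of the bins covered in every library, and tested between genotypes with limma 3.58.1 in R 4.3.3, with trended and robust variances, separately for each mark and with no block. Bins with a covered base in at least 3 H3K27ac or 2 H3K27me3 libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes are knockout minus control on this log2 scale, and where a group had no covered base their size depends on the pseudocount. In simulated data, 200 bins were changed by known amounts. Noise was drawn from a normal distribution with the variances that limma fitted, with no empty bins, and was tested with no filter and no centring. The shares below therefore check limma on its own model and do not cover bins without covered bases in a group. Of the changed bins among 19295 for H3K27ac, 24%, 56%, 66% and 78% were recovered at log2 changes of 1, 2, 3 and 4, with 7 false calls. For H3K27me3, with 21034 bins, the shares were 0%, 4%, 26% and 30%, with 9 false calls. The bins named in the text were, by a rule fixed before the data were examined, up to 10 per direction with the largest change among those past the threshold, and up to 5 regions per direction found in one genotype only, by the highest mean −log10 p. Loci singled out beyond that rule are said to be so. Called bins within 50 kb of each other and of the same direction were counted as 1 locus.

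The depth of a library is not stated in a peak list, but the fold and −log10 p of a peak fix its pileup and background for a Poisson model, so that the genome-wide background and the step of the pileup were read back from each list. Of 10 lists, 7 had pileups in whole fragments, and in these between 98.67% and 100% of peaks gave a whole pileup within a tolerance of 0.002 in −log10 p. The other 3 had a pileup scaled down to a smaller background library. With the narrowest peak taken as the fragment length, these values gave a relative depth in fragments per kb for the library and for its background library. The method was checked on 3 simulated lists.

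Alternatives fixed before the data were examined were a stricter threshold of −log10 q of at least 5, lists cut to equal length by −log10 p (21326 peaks for H3K27ac, 7512 for H3K27me3), a peak covering at least 50% of a region, merging of peaks within 500 bp, pseudocounts of 10 and 1000 bases, no filter, no centring, quantile normalization, the replicate number as a block, and leaving out each library in turn. Bins of 5 kb and 50 kb, equal lists of the 3 H3K27me3 libraries whose peaks all passed a −log10 p of 9, the relation of the marks without 1 library, and leaving out each library on the bins tested with all libraries were added after seeing the data. Fisher's exact test was run on the overlap of control-only H3K27ac with knockout-only H3K27me3 regions, but its p is not reported: the marks share almost no bases in the knockouts, so regions acetylated there could hardly overlap, and the contrast is set by the choice of regions. Other tools were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.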

Results

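H3K27ac and H3K27me3 were mapped in regulatory T cells of control chimeras and of chimeras whose regulatory T cells lacked Slc31a1, the copper importer CTR1. The comparison asks how losing copper uptake relates to active and repressive chromatin in these cells. H3K27ac lists held 32012, 27986 and 29748 peaks in controls 1 to 3 and 28289, 24154 and 21326 in knockouts 1 to 3. H3K27me3 lists held 7512 and 43945 peaks in controls 1 and 2 and 36436 and 57728 in knockouts 1 and 2. Depth read back from the lists was 12, 8.5 and 9.0 fragments per kb in the H3K27ac controls and 11, 11 and 9.1 in the knockouts, means of 9.97 ± 2.13 and 10.3 ± 1.07 (SD, n = 3 each, exact permutation p = 0.8, two-sided). For H3K27me3 it was 12 and 17 in the controls and 12 and 22 in the knockouts.

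The background library behind the lists differed between the genotypes. Its depth was between 20.6 and 20.7 fragments per kb in all 5 knockout lists, of both marks. H3K27ac controls 2 and 3 had 13.1, H3K27ac control 1 and H3K27me3 control 2 had 16.1, and H3K27me3 control 1 had 0.764. The background library and the genotype therefore cannot be told apart in any comparison of these lists.

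The length of acetylated chromatin differed between genotypes by less than the spread between libraries. Mean peak number was lower and mean peak width higher in the knockout libraries, with neither difference reaching a p under 0.1. Bases under H3K27ac peaks came to 42.9 ± 0.536 Mb in controls and 42.3 ± 4.77 Mb in knockouts (SD, n = 3 each, exact permutation p = 0.7, two-sided). Peak number was 29915 ± 2018 in controls and 24590 ± 3502 in knockouts (SD, n = 3 each, exact permutation p = 0.2). The median width was 826 ± 17.8 bp in controls and 967 ± 85.2 bp in knockouts (SD, n = 3 each), with each knockout library above each control library, and its exact permutation p of 0.1 is the smallest that this design allows. The narrowest peak, taken as the fragment length, was 232, 246 and 234 bp in controls and 232, 279 and 264 bp in knockouts. What set the median widths was not tested. Peaks of 10 kb or wider numbered 172, 287 and 283 in controls and 206, 501 and 365 in knockouts, exact permutation p = 0.3. The difference in covered length turned direction when knockout 3 was left out, to 1.79 Mb more in the knockouts.

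**Figure D1:**
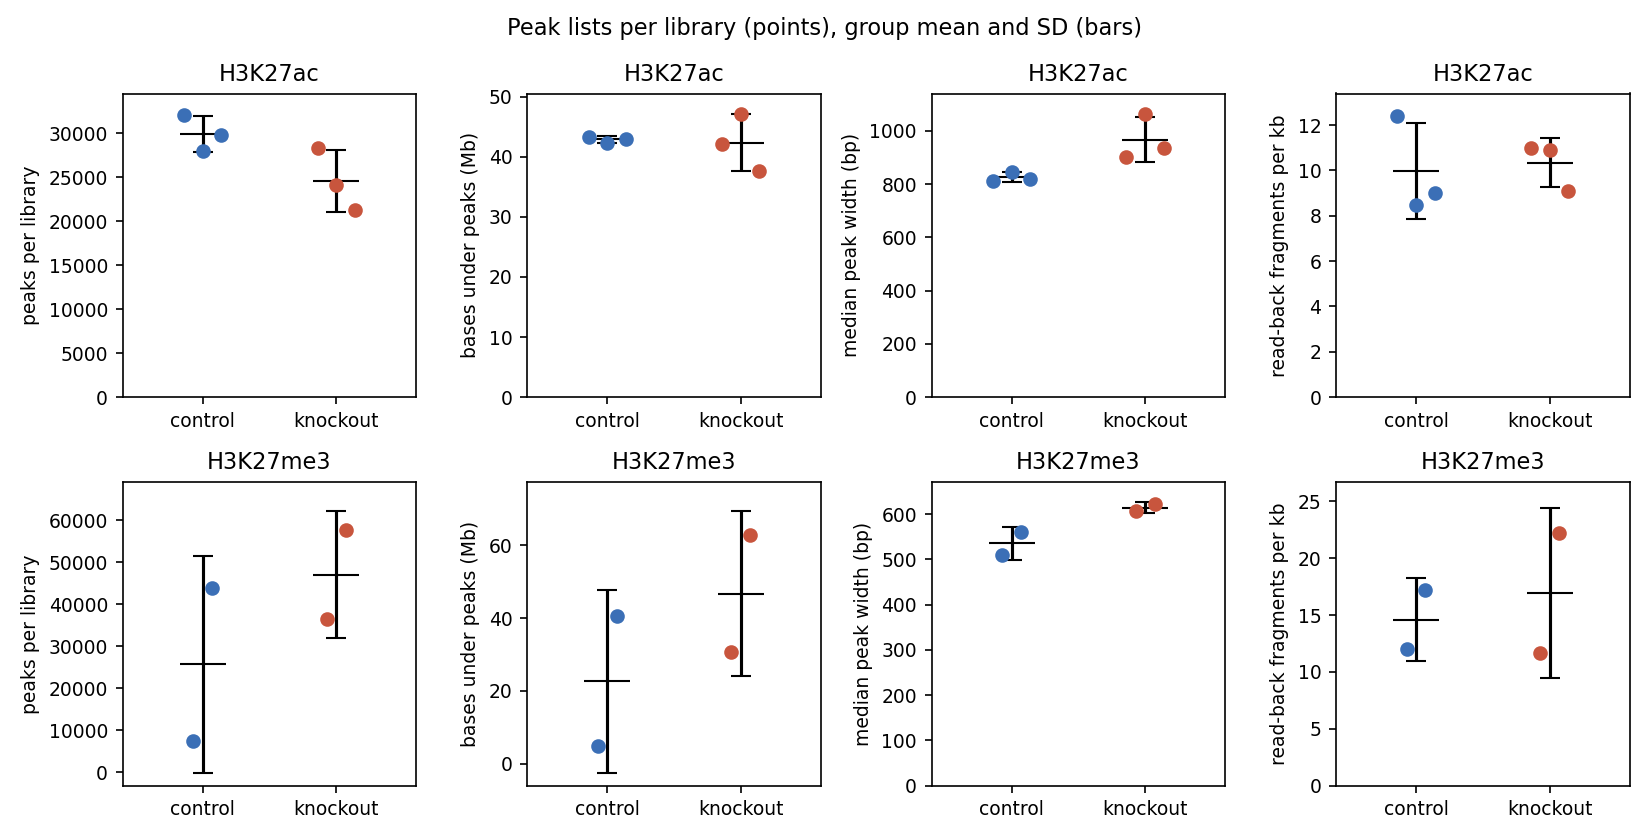
Peaks per library, bases under peaks in Mb, median peak width in bp and read-back depth in fragments per kb, for H3K27ac (upper row, 3 libraries per genotype) and H3K27me3 (lower row, 2 per genotype). Points are libraries and bars are the mean and SD. Median H3K27ac width is the measure on which the 3 knockout libraries all lie above the 3 controls, and H3K27me3 control 1 stands apart at 7512 peaks.

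Most acetylated regions that recurred were shared by both genotypes. Merging the 6 H3K27ac lists gave 37573 regions, of which 13106 (34.9%) had a peak in every library. A peak in all 3 controls and no knockout was found at 998 regions, and a peak in all 3 knockouts and no control at 304. These group-only regions held weak peaks: their median percentile of −log10 p within their own lists was 32.8 for control-only and 29.5 for knockout-only regions, against 69.8 for regions found in every library. The mean Jaccard index was 0.704 within and 0.660 between genotypes, the highest difference of the 10 splits (one-sided exact permutation p = 0.1, the smallest possible). Knockout 1 did not follow the means: its index with control 3, 0.697, was above that with knockout 3, 0.670. With lists cut to equal length, 489 regions were control-only and 455 knockout-only, a cut that by itself draws the counts together.

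**Figure D2:**
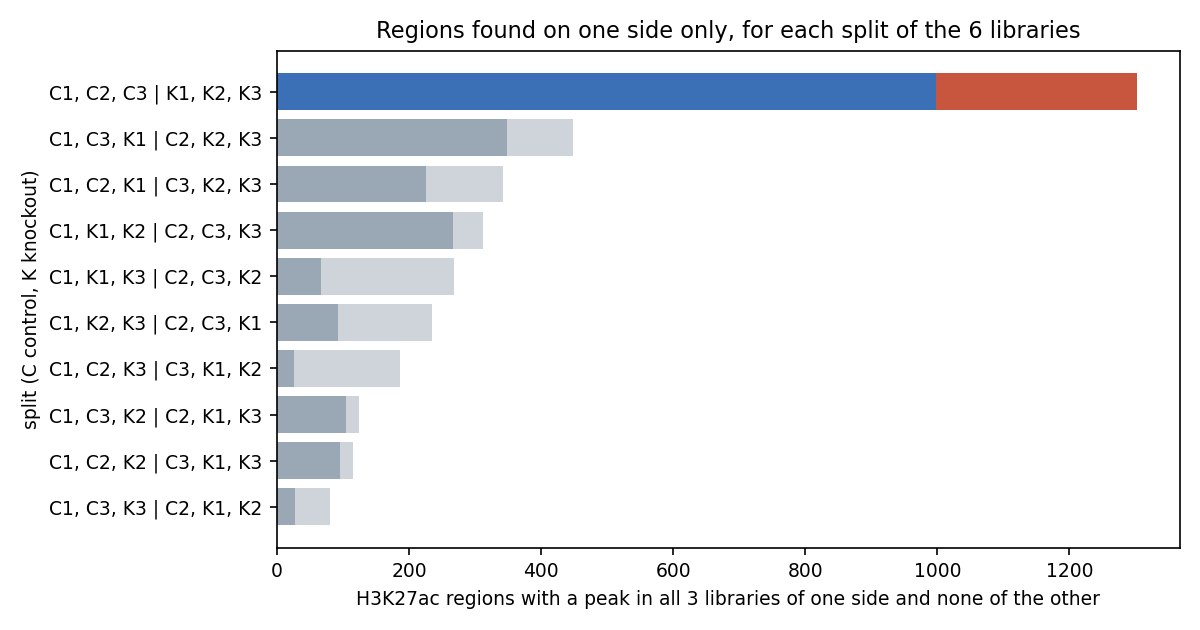
Number of H3K27ac regions with a peak in all 3 libraries of one side and none of the other, on the horizontal axis, for each of the 10 splits of the 6 libraries, listed on the vertical axis with the real grouping at the top. Blue and red parts of the real grouping are control-only and knockout-only regions, and darker and lighter grey the first and the second side of other splits. The real grouping gave 998 and 304 regions, 1302 in all, and the next highest split 448.

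The regions found in controls only with the highest mean −log10 p lay on chromosome 9 at 61726337 to 61729211, with 45.1 ± 12.1 over the 3 control lists, on chromosome 2 at 69934325 to 69936672, at 43.0 ± 10.5, and at 3 places near the end of chromosome X (SD, n = 3 each). The highest found in knockouts only were a pair on chromosome 4, at 63006307 to 63008944 with a mean of 53.0 ± 6.78 and at 62501113 to 62503520 with 49.7 ± 5.46. Regions on chromosome 19 at 38363482 to 38365625, with 36.8 ± 21.8, chromosome 10 at 93578602 to 93579702, with 31.4 ± 8.15, and chromosome 5 at 44292031 to 44293364, with 25.7 ± 14.2, followed (SD, n = 3 each). Slc31a1 itself lies on chromosome 4. Its position in the build of the lists was not used here, so H3K27ac at the targeted gene is not reported.

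By covered length, acetylation fell in more 10 kb bins than it rose. Of 19295 bins tested with limma, 435 were lower and 112 higher in knockouts at an adjusted p under the threshold, forming 345 and 97 loci, and the median log2 change over all bins was -0.05. With quantile normalization the counts were 349 and 168, and with lists of equal length 436 and 254. A pseudocount of 10 bases gave 26 lower and 4 higher, and no filter 269 and 58. With the replicate number as a block, 29 were lower and 3 higher. Nearly all calls were lost without any 1 control. In a refit on the same 19295 bins, chosen after seeing the data, limma called 5 lower and 3 higher without control 1, and 0 and 0 without control 2 or control 3, with 1567 lower and 868 higher, and 1699 and 1051, at an unadjusted p under 0.05. It called 974 and 245 without knockout 1, 20 and 0 without knockout 2 (719 higher at an unadjusted p under 0.05) and 67 and 0 without knockout 3 (852 higher).

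The largest falls were in a block near the end of chromosome X. Of the 10 bins with the largest falls, 8 lay between 169170001 and 169310000. The bin from 169290001 to 169300000 had 9572 ± 371 bases under peaks in controls (SD, n = 3) and 0 in each knockout, a log2 change of -6.62 (SE 0.249, limma adjusted p = 0.000345). On the same bins, its limma adjusted p was 0.0405, 0.119 and 0.0724 without control 1, 2 and 3, at log2 changes of -6.64, -6.58 and -6.63. Across the 7 called bins from 169250001 to 169320000, controls had 48384 ± 3816 covered bases and knockouts 0 (SD, n = 3 each). Block peaks of 2 kb or wider were weak for their width, with median −log10 p percentiles of 9.14, 8.60 and 8.84 among peaks of like width in the lists of controls 1 to 3. The remaining 2 were on chromosome 7 at 25480001 to 25490000, with 4088 ± 189 bases in controls and 0 in knockouts, and on chromosome X at 100770001 to 100780000, with 4113 ± 1043 and 0. Both lost their call with a pseudocount of 10 bases (limma adjusted p = 0.0529 and 0.0530). On the same bins, the chromosome 7 call was also lost without control 1, 2 or 3 (limma adjusted p = 0.0893, 0.130 and 0.117). So was that on X (0.0942, 0.130 and 0.117). Both stayed called with the replicate block (0.0376 and 0.0378) and without any 1 knockout. Longer runs of lower bins, singled out for their length after the values were seen, lay on chromosome 11 from 107980001 to 108100000, with 5 called bins and, over the whole stretch, 30958 ± 2201 covered bases in controls and 11526 ± 1999 in knockouts. On chromosome 17 from 73410001 to 73490000, with 5 called bins, the whole stretch had 40548 ± 1225 and 24336 ± 2581, and on chromosome 18 from 80680001 to 80730000, with 4, it had 26531 ± 4986 and 5662 ± 1046 (SD, n = 3 each).

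The largest rises included a stretch of chromosome 10 and a bin on chromosome 4. From 93480001 to 93580000 on chromosome 10, 6 of 10 bins were called higher. The whole stretch, with the uncalled bins that hold peaks of both genotypes, had 31729 ± 4481 covered bases in knockouts and 9875 ± 221 in controls (SD, n = 3 each). The bin on chromosome 10 from 93540001 to 93550000 had 2365 ± 459 bases in knockouts and 0 in controls, a log2 change of 4.58 (SE 0.477, limma adjusted p = 0.0171). Its call was lost with the replicate block (limma adjusted p = 0.0575). On the same bins it was lost without control 1, 2 or 3 (0.0541, 0.119 and 0.0915) and without knockout 2 or 3 (0.0883 and 0.0516). The log2 change stayed between 4.54 and 4.62 in these fits. On chromosome 4, the bin from 63000001 to 63010000 had 2447 ± 51.3 bases in knockouts and 0 in each control, a log2 change of 4.65 (SE 0.477, limma adjusted p = 0.0171). The call on chromosome 4 was lost with the replicate block (limma adjusted p = 0.0544, log2 change 4.65) and with a pseudocount of 10 bases (0.0566). On the same bins, it was also lost without control 1, 2 or 3 (0.0541, 0.119 and 0.0915) and without knockout 2 or 3 (0.0838 and 0.0516). The log2 change was 7.92 with that pseudocount, which sets its scale, and between 4.56 and 4.73 in the refits, so its size hardly moved there. Bins on chromosome 6 from 49130001, chromosome 1 from 183800001, chromosome 19 from 38360001, chromosome 16 from 44170001 and chromosome 11 from 93960001 also had 0 bases in every control, with means of 1979, 1622, 1529, 1450 and 1240 bases in the knockouts. All 10 named rises lost their call with a pseudocount of 10 bases, at log2 changes between 6.24 and 7.92.

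**Figure D3:**
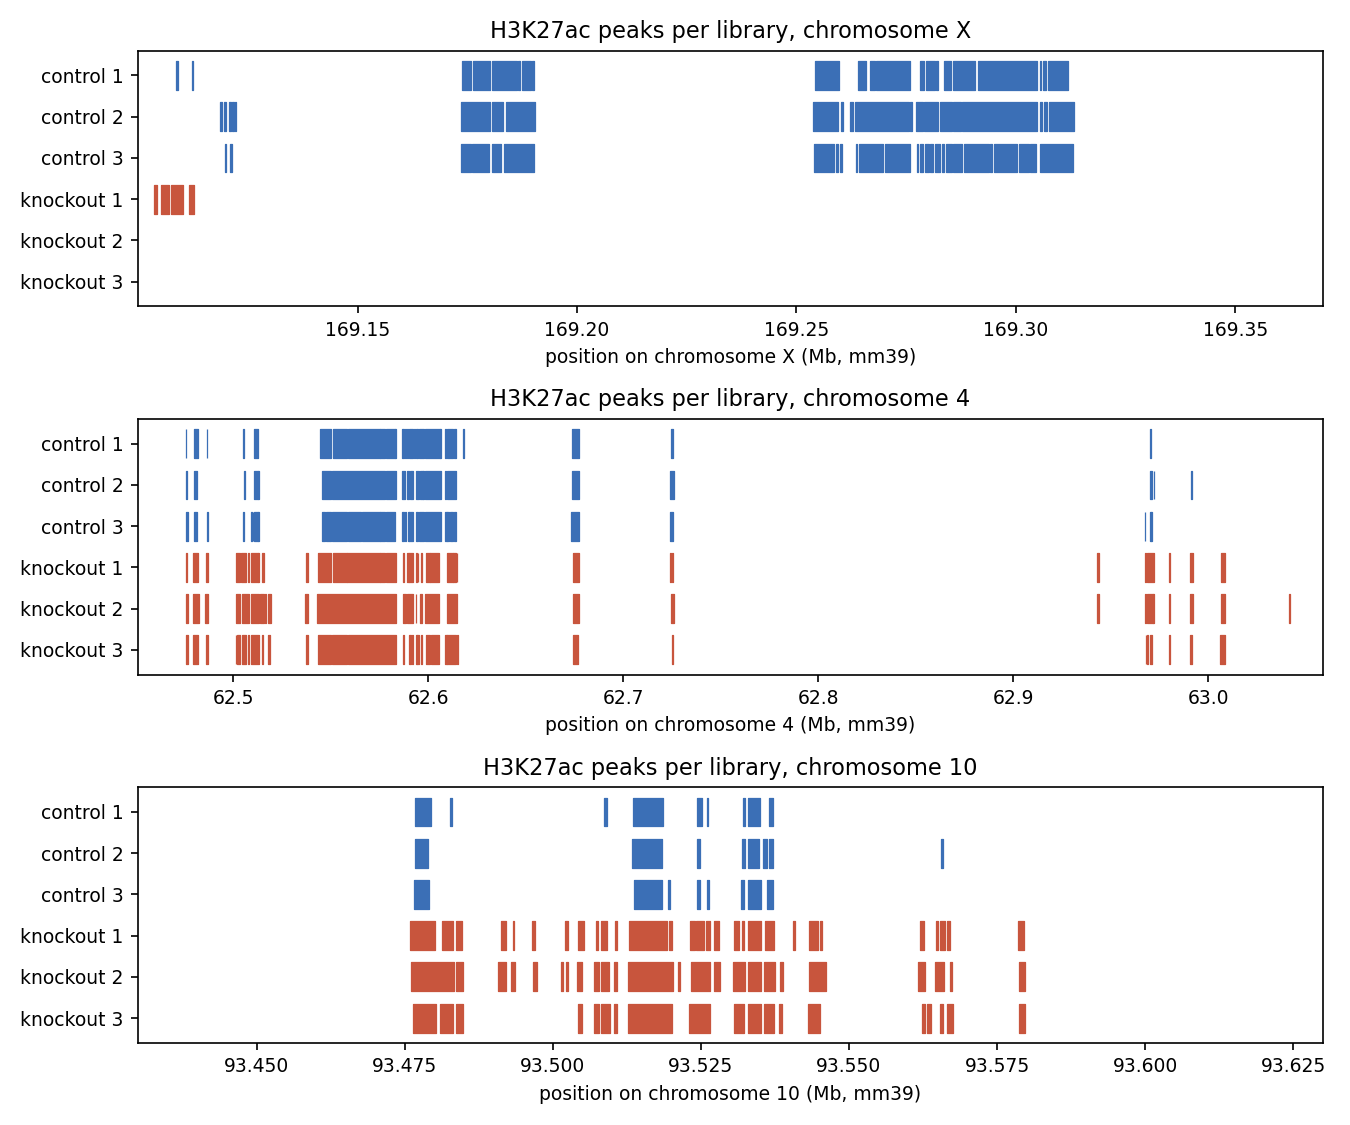
H3K27ac peaks of each of the 6 libraries as bars along the chromosome (horizontal axis, position in Mb, mm39) near the end of chromosome X, on chromosome 4 and on chromosome 10. Blue bars are control and red bars knockout libraries. From 169250001 to 169320000 on X the controls have peaks and the knockouts none, while on chromosome 10 from 93480001 to 93580000 the knockouts have a mean of 31729 covered bases against 9875 in the controls.

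H3K27me3 peaks were more numerous and covered more bases on average in knockouts, with overlapping values, and 1 control list stood apart. The list of control 1 started at a −log10 p of 2.02 and reached 7.21, with 4.89 Mb under peaks, while each of the other 3 lists started above 9 and covered between 30.6 and 62.8 Mb. Its peaks lay where the others had peaks: 95.9% overlapped control 2, 64.8% knockout 1 and 98.0% knockout 2, against 2.86% for control 2 after random placement. Peak number was 25728 ± 25760 in controls and 47082 ± 15060 in knockouts, and covered length 22.7 ± 25.1 and 46.7 ± 22.7 Mb (SD, n = 2 each, exact permutation p = 0.667 for both, where 0.33 is the smallest possible). Without control 1, the knockouts had 3137 more peaks and 6.27 Mb more under peaks, against 21354 and 24.0 Mb with it. The mean Jaccard index was 0.247 within and 0.256 between genotypes. The within mean joined 0.1105 for the controls and 0.384 for the knockouts. Control 1 had only 0.0773 and 0.075 with knockouts 1 and 2, so its short list weighed on both means. In turn, 13.1% of control 2, 12.6% of knockout 1 and 9.35% of knockout 2 peaks overlapped control 1.

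Few repressed regions were found in controls only when that list was included. Of 63341 merged H3K27me3 regions, 3861 (6.10%) were in every library, 27 in controls only and 6293 in knockouts only. Another split, setting control 1 and knockout 1 against control 2 and knockout 2, gave 9784. With control 2 as the only control, which by itself eases the rule for control-only regions, 5160 were control-only and 6305 knockout-only. With lists of equal length these were 574 and 903, and with equal lists of the 3 libraries other than control 1 the order turned, to 6513 and 5084. That last setting again asks for a peak in 1 control but in both knockouts, so the rule itself may have turned the order. Of 21034 bins, limma called 9 lower and 54 higher in knockouts, against 330 and 51 with quantile normalization, and 0 and 0 with lists of equal length (559 and 177 at an unadjusted p under 0.05). It called 1 and 0 with a pseudocount of 10 bases (983 higher at an unadjusted p under 0.05), 0 and 0 with 1000 bases (578 and 671), and 4 and 11 with no filter. Without centring it called 0 and 0 (2 and 556), and the median log2 change over all bins moved from 0.78 to 1.82.

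Among the named H3K27me3 bins, the largest rise was on chromosome 2 from 69960001 to 69970000, with 4903 ± 1339 covered bases in knockouts and 0 in controls, a log2 change of 4.58 (SE 0.888, n = 2 each, limma adjusted p = 0.00139). This call was lost with a pseudocount of 10 bases (limma adjusted p = 0.529), with 1000 bases (0.0760) and without centring (0.699), at log2 changes of 7.81, 1.85 and 5.62. The next, on chromosome 16 from 90120001 to 90130000, had 4631 ± 859 and 0, and its call was lost under the same 3 settings and with lists of equal length (limma adjusted p = 0.604), at log2 changes of 7.74, 1.79, 5.55 and 3.28. For both rises, the 0 in control 1 carries little weight. Between 9.35% and 13.1% of the peaks of each other list overlapped its short list. The largest fall was on chromosome 8 from 124530001 to 124540000, with 776 and 3975 bases in the controls and 0 in both knockouts. Its call was lost with a pseudocount of 10 bases (limma adjusted p = 0.522), with 1000 bases (0.1997), without centring (0.699) and with lists of equal length (0.47), at log2 changes of -8.57, -2.26, -4.24 and -4.95 against -5.28. Some called falls rested on knockout 1: on chromosome 15 from 75870001 to 75880000, knockout 1 had 0 bases while knockout 2 had 8885, above the 4480 and 8840 of the controls.

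The marks occupied separate parts of the genome in both genotypes. In chimera 2 of each genotype, which gave libraries of both marks, 0.0128% of H3K27ac bases in the control and 0.0203% in the knockout also lay under H3K27me3. Random placement of the H3K27me3 peaks gave 1.71% (range 1.57 to 1.88%) and 2.54% (2.38 to 2.74%) over 20 placements. Across the 579 bins tested for both marks, changes of the marks had a Spearman correlation of -0.114 across bins, which are not independent replicates, and of -0.407 across the 69 bins left with lists of equal length. Of the 998 control-only H3K27ac regions, 2 overlapped a knockout-only H3K27me3 region, and 5 of the other 36575 did. Regions acetylated in knockouts could hardly overlap H3K27me3 there. The contrast is therefore set by the choice of regions and cannot show a change from one mark to the other.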

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

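Bins of 5 kb and 50 kb, leaving out libraries on unchanged bins, equal lists of 3 H3K27me3 libraries and the relation of the marks without H3K27me3 control 1 were chosen after seeing the data. The cause of the changes below was not tested, except that leaving out a library or shortening lists leaves less to test. Leaving out a library also eases the rule for regions found in one genotype only. Differences in H3K27ac peak number and similarity, and in H3K27me3 peak number and covered length, kept their direction under every alternative run. The H3K27me3 differences rested largely on control 1: without it they shrank from 21354 to 3137 peaks and from 24.0 to 6.27 Mb. The difference in H3K27ac covered length was between -2.98 and 1.79 Mb when 1 library was left out. The H3K27me3 similarity difference was between -0.185 and 0.308.

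H3K27ac control-only regions numbered 489 with lists of equal length, and between 1078 and 2005 without 1 library. Knockout-only regions numbered between 400 and 728 without 1 library. Since the rule is then eased, these higher counts do not weigh single libraries. H3K27ac bins lower and higher in knockouts numbered 436 and 254 with lists of equal length, 26 and 4 with a pseudocount of 10 bases, 619 and 169 with 1000 bases, 269 and 58 with no filter, 737 and 207 in 5 kb bins and 211 and 56 in 50 kb bins. Without 1 library, on the same bins or those still passing the filter, they ranged from 0 to 1368 and from 0 to 245. Leaving out 1 control drops bins covered only in controls from the filter, so that 292 of the 547 called bins were then tested. Of the 547 called bins, 378 stayed called with the stricter threshold, 309 with lists of equal length, 443 without centring and 360 with quantile normalization.

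H3K27me3 control-only regions numbered 0 with a −log10 q of at least 5, 574 with lists of equal length, 6513 with equal lists of 3 libraries (5084 knockout-only), and between 30 and 5160 without 1 library. Knockout-only regions numbered 903 with lists of equal length and between 6305 and 25385 without 1 library. Leaving out a library, equal lists of 3 included, eases the rule, so that these region counts do not weigh single libraries. H3K27me3 bins lower and higher numbered 0 and 0 with lists of equal length, 1 and 0 with a pseudocount of 10 bases, 0 and 0 with 1000 bases, 4 and 11 with no filter, 0 and 0 without centring, 330 and 51 with quantile normalization, 3 and 29 in 5 kb bins and 0 and 3 in 50 kb bins. Without 1 library they ranged from 0 to 829 and from 27 to 5799, with 1 genotype then left with 1 library and all spread taken from the other, so that these counts do not weigh single libraries. At an unadjusted p under 0.05 limma gave 983 higher with 10 bases, 578 and 671 with 1000 bases, 2 and 556 without centring and 317 lower in 50 kb bins. The stricter threshold emptied the list of control 1, so that its bins could not be tested. The correlation of the marks across bins was -0.407 with lists of equal length.

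Whether the replicate numbers pair the H3K27ac samples stays open. Deviations of same-numbered libraries correlated at 0.246, 0.053 and 0.010. The first was the highest of any control with any knockout, while controls 2 and 3 correlated best with knockouts 3 and 2 (0.177 and 0.0886). With the replicate block, 29 H3K27ac bins were lower and 3 higher, and 9 and 62 H3K27me3 bins. Sign-flip tests within numbers gave an exact p of 0.25 for H3K27ac peak number, lower in 3 of 3 pairs, and 0.75 for covered length, and 0.5 for both with H3K27me3. Tests with other gene windows, other promoter windows and gene lists were not run, since no annotation of the build was used. The lists give no counts per region, and a region without a peak is one without a call at the authors' threshold, not one without signal.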

Other observations

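Lists of equal length were fixed before the data were examined, but their use to weigh list length was chosen after the result was seen, and the reading of their ratio was changed from a fit to open once it was known. Also chosen after were the tests of background library, other splits and extra copies. Those of depth, −log10 p percentile in the X block and windows of chromosome 4 were written before the value tested was seen.

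The spread of regions found in one genotype only was not tested, and the windows here are the extremes of all 2 Mb windows. Those from 16000001 on chromosome 12 and from 104000001 on chromosome 7 each held 10 control-only H3K27ac regions and 0 knockout-only ones, of 75 and 60 regions. Knockout-only regions were most numerous from 92000001 on chromosome 10, with 8 of 106, and from 98000001 on chromosome 12, with 7 of 117. By chromosome, control-only regions made up 4.25% of the 988 regions of chromosome 18 and 1.52% of the 1050 of chromosome 19, and knockout-only regions 1.51% of the 2123 of chromosome 10.

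The 4 background depths read back from the lists follow the chimeras that have an IgG sample in the labels. Those samples are control chimeras 1, 2 and 3 and 1 knockout chimera. The lists of control chimera 1 had 0.764 fragments per kb, those of control chimera 2 had 16.1, those of control chimeras 3 and 4 had 13.1, and all knockout lists had between 20.6 and 20.7.

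More H3K27ac regions were found in controls only (998) than in knockouts only (304). Deeper control libraries as the whole cause are argued against by comparing controls 2 and 3 with knockouts 2 and 3. There 2895 regions were control-only and 1054 knockout-only, a ratio of 2.75. Each of these knockouts was the deeper, but knockout 3 only slightly, at 9.10 fragments per kb against 9.02 in control 3. Longer control lists stay open. With lists of equal length the ratio was 1.07, but equal numbers of peaks draw the counts together whatever the cause, and bins on those lists still gave 436 lower and 254 higher. A background library that differs with genotype stays open and cannot be told apart from it. The local background at shared regions, over the genome background, was 3.99 ± 0.288 in knockouts and 3.74 ± 0.707 in controls (SD, n = 3 lists each). The ratio was 1.07, with overlapping values. The 3 knockout lists had background depths between 20.6 and 20.7, and controls 2 and 3 both had 13.1. Lists may thus share a background library, and the SD is no spread between separate backgrounds. The real grouping gave 1302 group-only regions and 547 called bins, the highest other split 448 and 1, and 1 of the 10 splits gave as many in each case, which is too few splits for a share under 0.05. A loss of acetylation with copper uptake stays open and was not tested apart from these.

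The H3K27ac block at the end of chromosome X, from 169170001 to 169320000, had 19, 16 and 24 peaks in the controls and 0 in each knockout. A stretch read at even depth, rather than acetylated peaks, is a candidate explanation: block peaks of 2 kb or wider had median −log10 p percentiles of 9.14, 8.60 and 8.84 among peaks of like width in the same list. Extra copies of the sequence in the control chimeras stay open, since the local background there was 1.62, 1.46 and 1.63 times the genome background. Controls 2 and 3 had the same background depth, 13.1 fragments per kb, and may share a background library. The values may therefore not speak for each chimera. A strain difference between the chimeras was not tested. A loss of acetylation with Slc31a1 also stays open.

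A window of chromosome 4, the chromosome of Slc31a1, held the 2 knockout-only H3K27ac regions with the highest mean −log10 p. From 62000001 to 64000000 it had 5 knockout-only regions and 1 control-only region among 74. Sequence carried along with the targeted allele may account for them. Although 2 other windows held more, with 8 and 7 knockout-only regions, a count of windows cannot weigh that explanation. The position of the gene in this build was not used, so that such sequence cannot be told apart from a response to the deletion.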
